A study of Mus musculus with 10 samples.

How the data were processed

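Single mouse embryos were compared on Affymetrix expression arrays, with 1 array for each of 5 wild-type and 5 Klf5 knockout embryos. Per the labels' protocols, cDNA was made from the RNA of individual embryos and amplified by the method of Kurimoto and colleagues. That protocol serves very small amounts of RNA and yields short products from near the 3′ end of transcripts. Per the labels' protocols, the material was labelled with biotin after the Affymetrix manual, and per the series' description expression was analysed in GeneSpring GX. Background correction, summary of probes into probe sets and normalization between arrays are not given in the sources used here. The deposited values were intensities on a linear scale, 1 per probe set and array, as judged from the values: all were above 0, the array medians lay between 39.9 and 43.5 and the highest values between 24149 and 32030. Whether the arrays were scaled before deposit is not known, although their medians were close. Detection calls were not used here. Genotype and embryo number were taken from the labels. No label ties an embryo to a litter or a culture, so the p-values measure the spread between these single embryos.

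The table held 38676 probe sets, of which 53 were Affymetrix controls and were left out of the tests. Gene names came from the platform's annotation table: 30854 probe sets had 1 gene symbol, 781 had several and 6988 had none. Probe sets with several symbols were not named. Of those with 1 symbol, 30697 were found by their gene identifier in the reference gene table, and 0 symbols changed. No genomic positions are given, because the annotation names no genome build for the array.

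Intensities were transformed as log2(intensity + 16), and probe sets whose mean over the 10 arrays was below the 40th percentile (5.55 on that scale) were left out, which left 23174. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. In a simulation on 23174 probe sets with the spread of these arrays, 16%, 60%, 96% and 100% of probe sets changed by 0.5, 1, 2 and 4 log2 units were recovered (50 of each size), and 13 of 149 calls were false. The difference in Klf5 was also tested by an exact two-sided permutation of the embryos. For gene lists, each of the 12518 genes was represented by its probe set with the highest mean, and Benjamini-Hochberg adjustment was made over all probe sets and over the list alone. Adjustment over the list alone makes no correction for the number of lists. Lists with at least 5 tested genes were tested with camera (preset correlation of 0.01), with camera using a correlation estimated from the data, and with fry in its directional and mixed forms, adjusted over 22 lists.

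The 24 gene lists, the rule for named genes, the tests and most alternatives were chosen before the data were examined. The lists held 451 names, of which 1 was not matched to a gene, 394 were in the table and 335 were tested. They covered trophectoderm regulators, trophectoderm epithelium and cavitation, epiblast, primitive endoderm, FGF and ERK, Kruppel-like factors, Hippo, polarity, oocyte and maternal-effect transcripts, activation at the 2-cell stage, apoptosis, stress, cell cycle, glycolysis, respiratory chain, cholesterol and lipid synthesis, ribosomal proteins, chromatin, and WNT, BMP and NODAL signalling. Further lists covered cumulus and granulosa, oviduct, blood and immune cells, Y-linked transcripts and X inactivation. Named genes are Klf5, then per direction the 10 largest differences among probe sets that passed, had a single symbol and separated the genotypes fully, with 1 probe set per gene. The lineage genes Cdx2, Eomes, Gata3, Nanog, Sox2, Pou5f1, Fgf4, Gata6, Sox17, Pdgfra, Klf2 and Klf4 follow, with the 3 members of smallest p in each list. Cdh1, Atp1b1, Dsp, Sparc, Dab2, Mdm2, Etv5 and the remaining list members that passed over the list alone (Krt7, Lgals3, Aqp3, Pkp2, Lamb1, Tead1) fall outside this rule and were chosen after their values were seen.

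The control probe sets were examined for technical sets of arrays. The mean of the 6 bioB probe sets split the arrays into 5 and 5 with a gap of 1.66 log2 units, the high set with 3 WT and 2 KO and the low set with 2 WT and 3 KO embryos. The gap between sets was used as a block, and the sets were also fitted alone. These fits, the fit without WT4 and WT5, and the fits with the 90th percentile of intensity or the 3′ minus middle difference of the lys spike as a covariate were added after the data were seen.

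The alternatives chosen beforehand were quantile normalization, centring on the array median, no level filter or a filter at the 60th percentile, and pseudocounts of 1 and 64. An intensity trend with a robust prior, array weights, the embryo number as a replicate block, the Y-linked level as a covariate and leaving out each embryo in turn were among them, as were an adjusted p of 0.1, an absolute difference of at least 1, counting 1 probe set per gene, and the mean of a gene's probe sets. A gene or list that passed in neither fit counts as keeping its side of the threshold whatever its sign, and counts of probe sets within 1.5 times the main count are taken as alike. A value was picked out for a closer look where the gap between 1 embryo and the nearest of its genotype exceeded the critical share of the range, 0.71 for 5 embryos, by Dixon's test. Groupings of the embryos other than by genotype were fitted for 100 drawn splits.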

Results

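Gene expression was measured in 10 single mouse embryos at 3.0 days post coitum, when the outer trophectoderm epithelium and the inner cell mass are being set apart. The embryos, collected from the oviduct, were 5 wild-type (WT) embryos and 5 embryos in which Klf5, a Kruppel-like zinc finger transcription factor, had been knocked out (KO). Each embryo was hybridised to its own Affymetrix array, and embryos are named by genotype and number (WT1 to WT5, KO1 to KO5). The array medians of the deposited intensities lay between 39.9 and 43.5. The 90th percentiles lay between 420 and 550, with a mean of 491 ± 64 in WT and 504 ± 25 in KO embryos (SD, n = 5). The number of arrays, 5 per genotype, limits the precision of every value. Levels are given as log2(intensity + 16) and differences as KO minus WT on that scale, which understates the change of dim probe sets.

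The first question was whether the targeted transcript was lower in the embryos labelled as knockouts. The brightest Klf5 probe set fell from 11.31 ± 0.84 in WT to 5.27 ± 0.45 in KO embryos (SD, n = 5), a difference of -6.04. The KO level lies under the filter level of 5.55, so the size of the difference depends on the pseudocount (-6.79 with 1, -4.89 with 64). In intensity, the WT embryos lay between 1096 and 4183 and the KO embryos between 14.0 and 49.2, so each embryo followed its label. The adjusted limma p was 0.000162, and the exact two-sided permutation p was 0.00794, the smallest that the 252 relabellings can give. A further tested Klf5 probe set did not follow it. Its level was 9.20 ± 0.37 in WT and 9.91 ± 0.36 in KO embryos (difference 0.71, adjusted p = 0.248, exact permutation p = 0.0317, n = 5). The other Klf5 probe set was below the level filter, at 4.90 in WT and 4.81 in KO embryos. The labels do not say which part of the gene was deleted, and a probe set outside that part checks nothing.

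By their control probe sets, the arrays formed 2 sets that the genotype does not explain. The bioB hybridisation control, a bacterial transcript added at hybridisation, read between 8.36 and 8.95 on WT1, WT2, WT3, KO1 and KO2 and between 6.16 and 6.69 on WT4, WT5, KO3, KO4 and KO5. The bioC, bioD and cre controls did not separate these sets. The lys spike, an added bacterial RNA with probe sets along its length, also separated them. Its 3′ minus middle difference was 2.13 to 2.70 in the high-bioB arrays and 3.02 to 4.46 in the low-bioB arrays, with the largest values in WT4 (3.93) and WT5 (4.46). The 3′ minus middle difference of actin was likewise largest in WT4 (4.61) and WT5 (3.96) and lay between 2.68 and 3.51 in the other 8 embryos. Over the tested probe sets, the first principal component (24.8% of variance) set WT4 (63.5) and WT5 (49.5) apart from the other 8 arrays (-28.3 to 0.67). The genotypes separated on the second (18.7%), at 8.49 to 39.2 in WT and -35.0 to -15.4 in KO embryos. WT1 to WT3 correlated with WT4 and WT5 at 0.928 to 0.943, and WT with KO embryos at 0.925 to 0.958. Both bioB sets hold embryos of both genotypes, so results are also given with the set as a block and within each set. The block takes the difference between the sets to be the same in both genotypes. The sets differed at 844 probe sets among WT embryos and at 0 among KO embryos, with the interaction past the threshold at 0. Results with the block rest on that assumption.

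**Figure D1:**
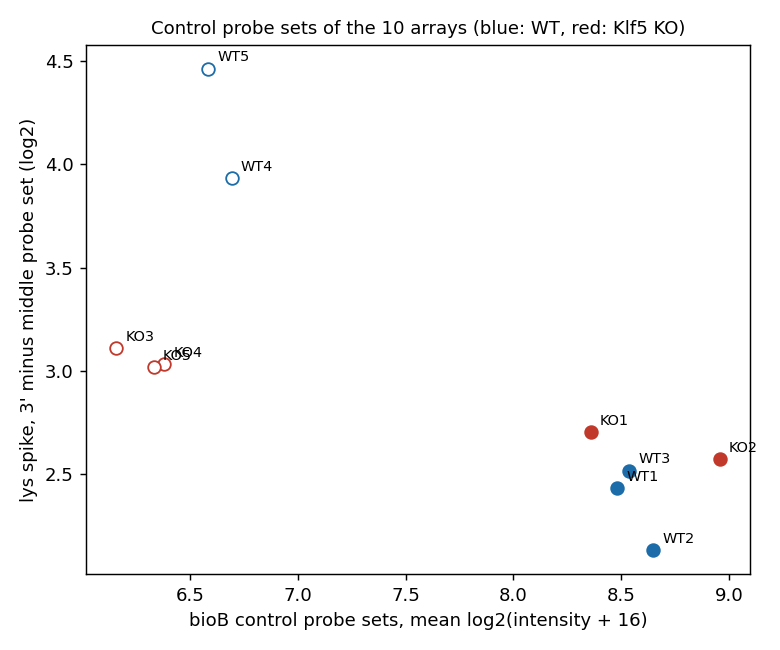
Mean log2(intensity + 16) of the bioB control probe sets (x axis) against the 3′ minus middle difference of the lys spike (y axis, log2) on each of the 10 arrays, with WT in blue and KO in red. Filled points are the high-bioB arrays and open points the low-bioB arrays, and WT4 and WT5 lie highest on the y axis, at 3.93 and 4.46.

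The main comparison asked which transcripts differ between KO and WT embryos of this stage. Klf5 aside, Gsn and Krt8 were among the transcripts that fell most in KO embryos. Gsn, which encodes the actin-severing protein gelsolin, fell from 11.08 ± 0.67 to 6.83 ± 0.96 (SD, n = 5; 19.1-fold, adjusted p = 0.00473). Krt8, a keratin of the trophectoderm intermediate filaments, fell from 13.26 ± 0.48 to 10.28 ± 0.43 (SD, n = 5; 7.88-fold, adjusted p = 0.00118). Among the transcripts that rose was Cubn, which encodes the endocytic receptor cubilin of visceral endoderm and absorptive epithelia, from 6.68 ± 0.39 to 8.82 ± 0.67 (SD, n = 5; 4.40-fold, adjusted p = 0.0241). Oat, the mitochondrial ornithine aminotransferase, rose from 7.22 ± 0.43 to 9.48 ± 0.31 (SD, n = 5; 4.80-fold, adjusted p = 0.00190).

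**Figure D2:**
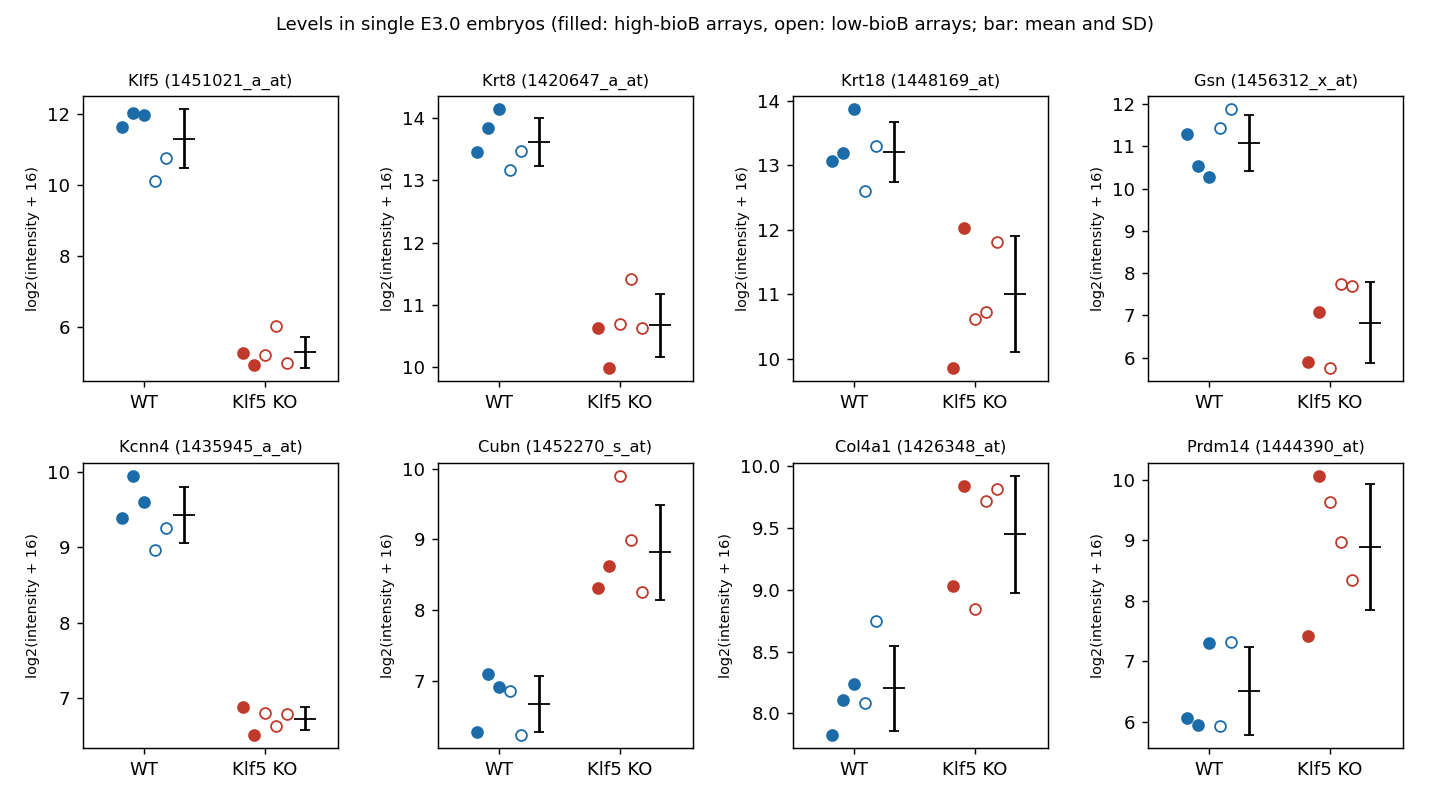
Levels of 8 genes in single embryos, as log2(intensity + 16), with WT in blue, KO in red, filled points for high-bioB arrays, open points for low-bioB arrays, and bars for the mean and SD of 5 embryos. The WT and KO embryos do not overlap for any of the 8 probe sets, Klf5 shows the widest gap (means of 11.31 and 5.27), and Krt18, Col4a1 and Prdm14 did not pass the adjustment over all probe sets.

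Of 23174 probe sets tested, 85 passed an adjusted limma p of 0.05. Of these, 28 were higher and 57 lower in KO embryos, and they stood for 71 genes, 23 higher and 48 lower. At an unadjusted p under 0.05 there were 2329 probe sets, 1208 higher and 1121 lower. In all 85 the KO embryos lay on one side of the WT embryos. That separation was met by 539 tested probe sets (2.33%), where chance gives 0.794%. With the bioB set as a block, 69 probe sets passed (23 higher, 46 lower), 57 of them shared with the 85. Within the high-bioB set alone 1 passed (2105 at an unadjusted p under 0.05) and within the low-bioB set alone 0 passed by limma (3512 unadjusted). These subsets of 3 against 2 embryos cannot give a permutation p below 0.1. Without WT4 and WT5, 73 passed (11 higher, 62 lower), 35 of them among the 85. The count was 56, 50, 63, 47 and 49 without WT1, WT2, WT3, WT4 and WT5 in turn, and 50, 45, 51, 54 and 61 without KO1, KO2, KO3, KO4 and KO5.

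**Figure D3:**
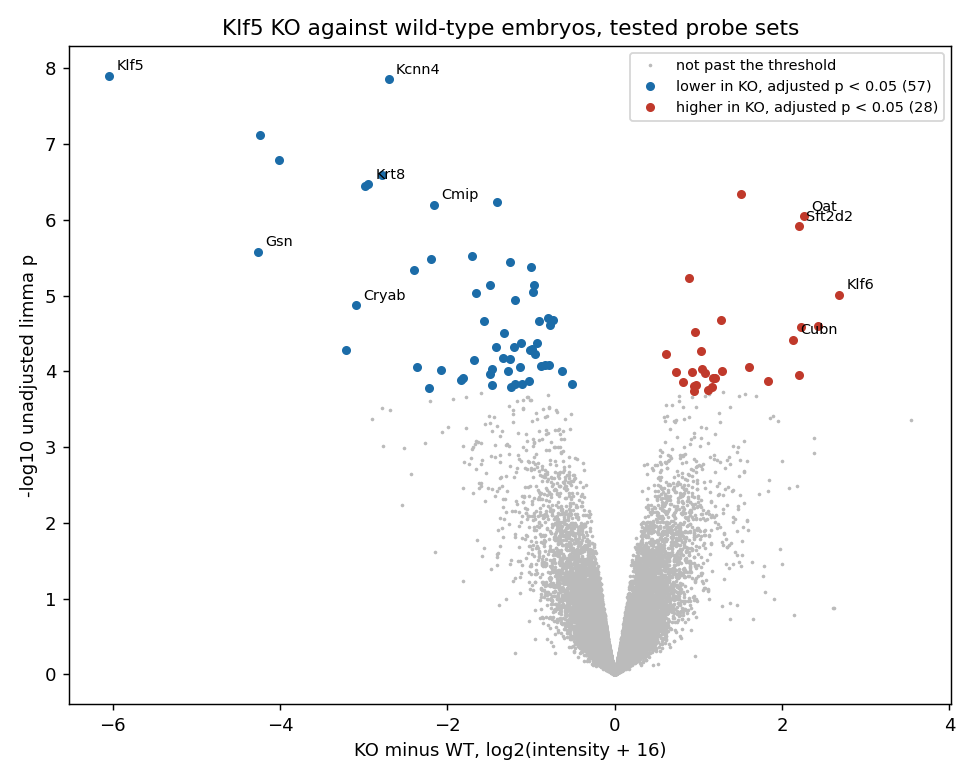
Difference between KO and WT embryos for each of the 23174 tested probe sets (x axis, log2(intensity + 16)) against the negative log10 of the unadjusted limma p (y axis), with probe sets past the adjusted threshold in blue (57 lower in KO) and red (28 higher in KO). Klf5 lies farthest to the left, at -6.04.

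Among the other large falls, Cryab, a small heat shock protein, differed by -3.09 (adjusted p = 0.0119) and Kcnn4, a calcium-activated potassium channel, by -2.70 (adjusted p = 0.000162). Myo1c, a class I myosin, differed by -2.39 (adjusted p = 0.00595), and Cmip by -2.16 (adjusted p = 0.00146). S100a10, a partner of annexin A2, differed by -2.36, Serpinb6c by -2.22 and Grtp1 by -2.08, with adjusted p between 0.0367 and 0.0458. All 4 tested Gsn probe sets (-4.26 to -2.19) and all 3 tested Krt8 probe sets (-2.98 to -2.78) passed. For Kcnn4 and Cmip, 1 of 2 probe sets passed and the other differed by only -0.22 and -0.40. Cryab, Myo1c, S100a10 and Grtp1 also passed at 1 of 2, and the other differed by -1.16, -1.05, -1.27 and -1.63. Within the high-bioB and low-bioB sets the differences were -4.21 and -4.61 for Gsn, -3.67 and -2.26 for Krt8, and -2.94 and -2.37 for Kcnn4. Without WT4 and WT5, Cryab (-2.74, adjusted p = 0.0639), S100a10 (-2.25, 0.113), Serpinb6c (-2.19, 0.115) and Grtp1 (-1.85, 0.118) no longer passed. With the bioB block, Serpinb6c did not pass (-2.30, adjusted p = 0.0620).

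Among the rises, Klf6, a Kruppel-like factor related to Klf5, rose at 1 of its 4 tested probe sets, from 5.0 ± 0.32 to 7.68 ± 0.77 (SD, n = 5; difference 2.68, adjusted p = 0.00944). The WT level lies under the filter level of 5.55, and the difference was 3.52 with a pseudocount of 1 and 1.68 with 64. Its other 3 probe sets differed by 0.39 to 1.31 and did not pass. Gyg, the primer of glycogen synthesis, rose by 2.43 (adjusted p = 0.0176) and Mlxipl, the carbohydrate-responsive transcription factor ChREBP, by 2.23 (adjusted p = 0.0176). Sft2d2 rose by 2.20 at one probe set (adjusted p = 0.00233) and by 1.51 at another, and 2 of its 4 probe sets passed. Zfp639 rose by 1.27 (adjusted p = 0.0164). Mical1, an actin-oxidising enzyme, rose by 2.21, Reep5, a protein that shapes the endoplasmic reticulum, by 1.83 and Plpp1, a lipid phosphatase, by 1.61, with adjusted p between 0.0367 and 0.0430. Reep5 passed at 1 of its 3 tested probe sets, and the others differed by -0.08 and 1.11. Mical1, Reep5 and Plpp1 did not pass with the bioB block (adjusted p = 0.0638, 0.0730 and 0.0565), at differences of 2.14, 1.79 and 1.63. Without WT4 and WT5, of these 10 genes only Gyg, Oat and Sft2d2 passed, and for the other 7 the adjusted p lay between 0.0516 (Klf6, 2.75) and 0.0801 (Cubn, 2.05).

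Of the 20 genes with the largest falls and rises, 11 passed whichever single embryo was left out. Gyg was lost only without WT2 (2.39, adjusted p = 0.0507) and Mlxipl only without WT4 (2.23, adjusted p = 0.0504). Cubn was lost without WT1, WT4, WT5, KO2 or KO4, with differences of 2.03 to 2.18 and an adjusted p of at most 0.0606. Grtp1 was lost in 7 of the 10 fits, S100a10, Plpp1 and Reep5 in 8, and Mical1 and Serpinb6c in 9, with adjusted p up to 0.119 (Serpinb6c without WT5, -2.10).

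None of the 12 lineage transcripts fixed by name passed the test. Cdx2, the trophectoderm homeobox factor, was at 9.08 ± 0.24 in WT and 8.80 ± 0.38 in KO embryos (SD, n = 5; adjusted p = 0.742). For the trophectoderm factors Eomes and Gata3 the differences were 0.26 and 0.47 (adjusted p = 0.952 and 0.669). Nanog, Sox2 and Pou5f1, the pluripotency factors, differed by 0.91, 1.06 and -0.29 (adjusted p = 0.815, 0.581 and 0.903). The SD of Nanog among WT embryos was 1.83, and its difference was -0.35 without WT4 and WT5. Gata6, Sox17 and Pdgfra, the primitive endoderm genes, differed by 0.39, -0.02 and 1.03 (adjusted p = 0.871, 0.990 and 0.496), and the direction for Gata6 turned to -0.28 without WT4 and WT5. Klf2 and Klf4 differed by 1.05 and 0.65 (adjusted p = 0.434 and 0.521). The differences of Klf2, Sox2, Gata3, Pdgfra and Pou5f1 were 0.44, 0.52, 0.14, 0.62 and -0.62 without WT4 and WT5. Fgf4, the growth factor ligand of the early epiblast, differed by 0.14 at its brightest probe set and by 1.46 and 1.51 at the others (adjusted p = 0.907, 0.397 and 0.442). With 5 embryos per genotype, a simulated change of 1 log2 unit was recovered for 60% of changed probe sets and one of 0.5 for 16%. Those probe sets were drawn at random from all tested ones. The standard errors of the lineage genes ran from 0.09 (Sox17) to 0.76 (Nanog), so these shares do not hold for each of them.

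Trophectoderm genes were next examined as 2 lists. In the list of epithelium and cavitation genes, 21 were tested, and adjusted over the list alone 4 were lower and 1 higher in KO embryos. The lower ones were Krt8 (-2.94), its partner keratin Krt18 (-2.20), the desmosomal Pkp2 (-0.97) and the water and glycerol channel Aqp3 (-0.78), and the higher one was the endocytic receptor Lrp2 (0.80). Over all probe sets tested only Krt8 of these passed, and Krt18 had an adjusted p of 0.0541. The other Lrp2 probe sets differed by 0.21 and 0.38, and at the listed one WT1 was low (8.87). The remaining 16, among them Cdh1 (-0.03), Atp1b1 (0.03) and Dsp (0.07), did not pass. In the list of transcription factors and regulators, 16 were tested, and adjusted over the list alone Tfap2c (-1.37), Tspan8 (-1.59), Krt7 (-1.19) and Lgals3 (-1.32) were lower and Plac1 (0.97) higher, with none past the adjustment over all probe sets. The KO levels of Tspan8 (5.10) and Krt7 (5.52) lie under the filter level, and the Tspan8 difference was -2.20 with a pseudocount of 1 and -0.92 with 64. Other probe sets differed by -0.99 and -0.30 for Tfap2c and by -0.38 for Tspan8. Without WT4 and WT5, none of these 4 lower regulators passed over the list alone, while Plac1 did, and in the epithelium list Krt8, Krt18 and Lrp2 still did. With the bioB block, all 5 regulators passed and Aqp3 did not. The camera test, which sets a list against other genes, did not pass for either list (adjusted p = 0.645 and 0.436; 0.875 and 0.703 with an estimated correlation). For the epithelium list the mean difference was -0.23, the median 0.03 and the direction of the test down.

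**Figure D4:**
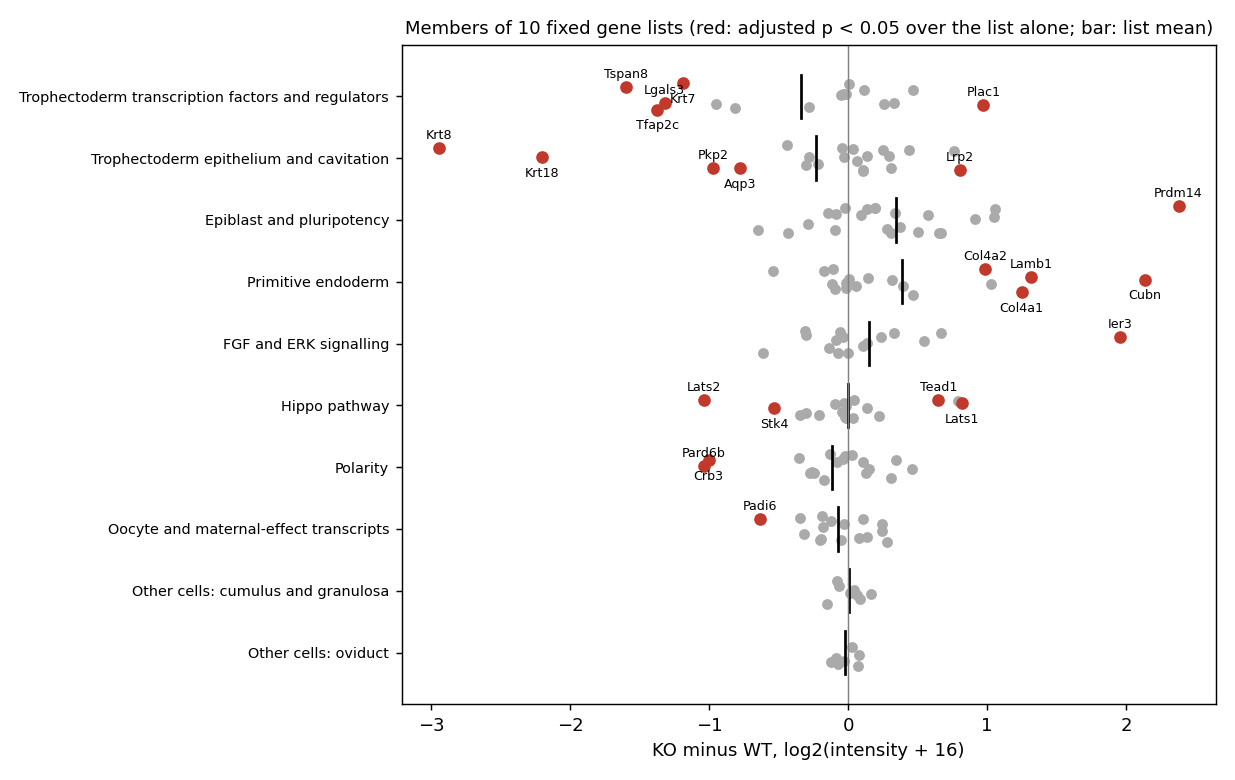
Difference between KO and WT embryos (x axis, log2(intensity + 16)) for each tested member of 10 gene lists (y axis), with members whose adjusted p over the list alone was under 0.05 in red and named, the others in grey, and a bar at the list mean. Krt8 (-2.94) and Krt18 (-2.20) lie farthest to the left and Prdm14 (2.38) and Cubn (2.14) farthest to the right.

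Of 18 primitive endoderm genes tested, 4 were higher in KO embryos when adjusted over the list alone, and 0 were lower. They were Cubn (2.14), Lamb1 (1.31), Col4a1 (1.25) and Col4a2 (0.99), the latter 3 being chains of the laminin and type IV collagen of basement membranes. Over all probe sets only Cubn passed, and Col4a1 had an adjusted p of 0.0659. The other Col4a1 probe set differed by 0.41. All 4 also passed over the list alone without WT4 and WT5. The mean difference of the list was 0.39 over all arrays, 0.37 in the high-bioB set and 0.48 in the low-bioB set, and the median was 0.10. Gata6, Sox17, Sparc (-0.01) and Dab2 (-0.11) did not pass. Pdgfra passed over the list alone with the bioB block (1.26, adjusted p = 0.00979; 1.43 and 1.10 in the high-bioB and low-bioB sets, 0.03 at its other probe set), though not without the block or without WT4 and WT5 (adjusted p over the list 0.179 and 0.517). The camera test of the list did not pass after adjustment over 22 lists (p = 0.00384, adjusted p = 0.0845; adjusted p = 0.310 with an estimated correlation). It passed with the bioB block (adjusted p = 0.0173), and without WT4 and WT5 the adjusted p was 0.334. By fry, which asks whether the members move on balance one way, its adjusted p was 0.00197 (0.287 without WT4 and WT5).

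Of 23 epiblast and pluripotency genes tested, 1 was higher in KO embryos when adjusted over the list alone, Prdm14, a regulator of naive pluripotency, from 6.51 ± 0.73 to 8.89 ± 1.05 (SD, n = 5; difference 2.38, adjusted p = 0.0991 over all probe sets). Without WT4 and WT5 its adjusted p over this list was 0.0770. The mean difference of the list was 0.35, with 16 members higher and 7 lower, and the camera test did not pass (p = 0.00874, adjusted p = 0.0962; adjusted p = 0.875 with an estimated correlation). It passed with the bioB block (adjusted p = 0.00803), and without WT4 and WT5 the adjusted p was 0.948. The list mean difference was 0.20 in the high-bioB set and 0.68 in the low-bioB set. Among WT embryos alone it was lower in WT4 and WT5 than in the other 3 by a mean difference of -0.69 (camera adjusted p = 0.00456), and among KO embryos the low-bioB arrays differed by -0.21 (adjusted p = 0.147). The cell cycle list (-0.68, adjusted p = 0.0285) and the DNA methylation and chromatin list (-0.54, adjusted p = 0.0194) were also lower in WT4 and WT5. With an estimated correlation none of the 3 lists passed among WT embryos (adjusted p = 0.372 for each, unadjusted p = 0.0263, 0.0507 and 0.0421 for epiblast, cell cycle and chromatin).

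Single members stood out in the lists of signalling and cell organisation, again adjusted over the list alone. Of 16 FGF and ERK genes, Ier3, an immediate early gene of ERK signalling, was higher by 1.95, while Fgfr1 (0.54) and Fgf3 (-0.31) did not pass. Of 18 Hippo pathway genes, Lats1 (0.82) and Tead1 (0.65) were higher and Lats2 (-1.03) and Stk4 (-0.53) lower, Lats2 at only 1 of 4 probe sets (0.02 to 0.12 at the others). Lats1, Lats2 and Stk4 are kinases of this pathway, and 0 members passed without WT4 and WT5, and with the bioB block only Lats1 did. Of 18 polarity genes, the apical proteins Pard6b (-1.04) and Crb3 (-1.0) were lower, and without WT4 and WT5 only Pard6b passed. The other Crb3 probe sets differed by -0.35 and -0.10, and that of Pard6b by -0.69. None of these FGF and ERK, Hippo and polarity genes passed over all probe sets. Of 12 other Kruppel-like factors, 14 WNT, BMP and NODAL genes, 14 apoptosis genes and 21 cell cycle genes, 0 passed over the lists alone, where each gene was read at its brightest probe set (Klf6 at 0.39, not at the probe set that rose). In the apoptosis list Perp (-1.76) and Mdm2 (-0.51) passed without WT4 and WT5 (adjusted p over the list 0.0477 for both), and in the FGF and ERK list Etv5 passed with the bioB block (0.84, 0.0304), as it did in the epiblast list (0.0437). The WNT, BMP and NODAL list had a mean difference of -0.18 (limma camera, adjusted p = 0.273; adjusted p = 0.703 with an estimated correlation).

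Other groups showed few members past the test. Of 16 oocyte and maternal-effect transcripts, Padi6, a component of the oocyte cytoplasmic lattices, fell by 0.63 (adjusted p = 0.0371 over all probe sets). Padi6 did not pass with the bioB block (-0.64, adjusted p = 0.0540), without both WT4 and WT5 (-0.59, 0.104), or in 8 of the 10 fits that left out 1 embryo (adjusted p up to 0.0965), passing only without WT1 or KO5. Of 4 transcripts tested from the list of activation at the 2-cell stage, Sp110 was lower (-1.65) and Pramel13 higher (0.69) over the list alone. Pramel13 no longer passed without WT4 and WT5. Over all probe sets neither passed (limma adjusted p = 0.144 and 0.347), and the other Sp110 probe set differed by -0.31. In the stress list the antioxidant enzyme Nqo1 was lower over the list alone (-0.68, 17 tested), which was lost with the bioB block and without WT4 and WT5. Over all probe sets Nqo1 did not pass (limma adjusted p = 0.158). Hspa1a passed over the list only without WT4 and WT5 (-3.07, adjusted p over the list 0.0280). In the chromatin list Prdm14 was the 1 member that passed of 20 tested, and Kdm1a (-0.66) joined it without WT4 and WT5 (adjusted p over the list 0.0442). In the lists of 16 glycolysis, 20 respiratory chain, 18 cholesterol and lipid synthesis, 15 ribosomal protein and 10 X inactivation genes, 0 passed over the list alone, and Hprt of the last did so with the bioB block (0.57, 0.0132). The 1 Y-linked transcript tested, Sry, differed by 0.11 (adjusted p = 0.804). Its probe set read 6.96 in WT1 and 6.99 to 7.33 in the other embryos. The Y-linked Eif2s3y was raised only in WT1 (6.48), so the Sry probe set did not follow it and gives no measure of Y-linked expression.

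Markers of cells that could adhere to a flushed embryo had low list means in both genotypes. The means of the cumulus and granulosa, oviduct, and blood and immune lists were 6.56, 6.01 and 6.22 in WT and 6.56, 5.99 and 6.2 in KO embryos, with 8, 7 and 6 genes tested. Of these, Cd52, a leukocyte surface antigen, was lower in KO embryos when adjusted over the list alone (-0.47), though not without WT4 and WT5, and 0 passed in the other 2 lists. Over all probe sets Cd52 did not pass (limma adjusted p = 0.129). Alas2, a haem synthesis enzyme of red blood cells, was at 7.39 in KO4 and 7.16 in KO5 and between 5.54 and 6.12 in the other 8 embryos (difference 0.50, adjusted p = 0.755).

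By camera, 0 of the 22 lists with at least 5 tested genes passed after adjustment, with 3 at an unadjusted p under 0.05. With an estimated correlation 0 passed as well, with 1 at an unadjusted p under 0.05. By fry 1 list passed for a shift one way (primitive endoderm) and 7 for change in either direction. The 7 were both trophectoderm lists, primitive endoderm, FGF and ERK, Hippo, polarity, and oocyte and maternal-effect transcripts. Their adjusted p ran from 2.97e-08 (trophectoderm epithelium) to 0.00897 (FGF and ERK). Hippo did not pass this mixed test without WT4 and WT5 (adjusted p = 0.0599). Fry does not set a list against other genes, and few members can carry its mixed form. In the FGF and ERK and the oocyte lists, only 1 member each passed over the list alone (Ier3 and Padi6). The mean and median differed in sign for the trophectoderm epithelium, FGF and ERK (0.15 and -0.02), Hippo (0.00 and -0.02, the mean turning below 0 with quantile normalization), apoptosis (-0.01 and 0.00) and 2-cell (-0.24 and 0.01) lists. The direction of the camera test was up for FGF and ERK, Hippo and apoptosis.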

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

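The tests without WT4 and WT5, those of the lys spike and that of oviduct and connective tissue transcripts were chosen only after the result was seen, as was the bioB block itself. Dixon's test was run on 238 groups of 5 embryos, gave 13 outlying embryos, and by chance picks out about 1 in 20 groups. Among these, 5 were WT1. WT1 was low for Lrp2 (8.87, the other WT embryos 9.74 to 9.83), Padi6 (7.36, others 7.62 to 7.69) and Cd52 (6.07, others 6.33 to 6.43) and high for Wnt7b (9.61, others 8.13 to 8.50). Its Xist level was 6.73, the other WT embryos lying between 11.17 and 12.60. WT2 was high for Fgf3 (6.85, others 6.17 to 6.35) and Stk4 (10.94, others 10.12 to 10.27). WT4 was high for Crb3 (11.37, others 10.70 to 10.88) and low for Rps18 (13.66, others 14.20 to 14.31). KO5 was high for Cryab (7.64, others 5.61 to 6.10) and Cdc20 (13.49, others 13.15 to 13.21), and KO3 was high for Mlxipl (10.10, others 8.53 to 8.69). The mean of the trophectoderm epithelium list was low in KO4 (8.65, other KO embryos 8.92 to 9.03). Among probe sets below the level filter, Zfp974 was higher in KO embryos, at 5.85 against 5.20 in WT (adjusted p = 0.0316 in a fit of all probe sets). A further 3 below the filter passed in that fit and were lower, a Gsn probe set (-0.79, adjusted p = 0.0396), Mpzl2 (-1.29, adjusted p = 0.0401) and one with no gene symbol (-0.76, adjusted p = 0.0354).

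The 85 probe sets that passed between genotypes were set against 3 other explanations. Of 100 splits of the 10 embryos into 5 and 5, only the real one, 1 in all, gave as many. The highest of the others gave 3, which argues against a chance split. With the bioB block, 57 of the 85 still passed, and the split that follows the bioB sets gave 0 (2703 at an unadjusted p under 0.05), which argues against that batch as the whole cause. Without WT4 and WT5, 73 probe sets passed, 35 of them among the 85, and of the 56 splits of the other 8 embryos into 3 and 5 only the real one gave as many (highest other 5), which argues against these 2 arrays as the sole cause of such a count. A difference between genotypes is one hypothesis that remains for the group of 85, found and tested on the same data. Other differences that could go with the genotype labels, such as litter, are not given in the labels and were not tested.

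WT4 and WT5 differed from the other WT embryos at 844 probe sets, 784 of them lower, whereas the low-bioB and high-bioB KO embryos differed at 0 (853 at an unadjusted p under 0.05), and the interaction passed at 0 (2923 unadjusted). The lys spike had a 3′ minus middle difference of at least 3.93 in both arrays and at most 3.11 in the other 8, and because this RNA is added to the sample, shorter cDNA arising in processing is a candidate explanation. A shared effect of the bioB batch cannot be told apart from other causes, because the batch differences in KO and WT embryos correlated at 0.142 across probe sets, between the bounds of 0.1 and 0.3 set for it. A narrower intensity range of these arrays also stays open over all probe sets, since level explained 9.62% of the variance (bootstrap SE 0.404) and the bound was 10%. The epiblast list's median of -0.85 lay at percentile 0 of 10000 lists matched on level, below the bound set for it. Random lists do not carry the correlation between these genes, so this does not exclude the explanation for the epiblast list. By the mean, the epiblast list was lower by 0.69, the cell cycle list by 0.68 and the chromatin list by 0.54. With an estimated correlation none of the 3 passed (camera adjusted p = 0.372). No biological explanation was tested, since the labels give 1 age for all embryos and no litter or sex. Xist was at 12.6 and 11.2 in WT4 and WT5 and at 12.1 and 11.6 in WT2 and WT3. The Y-linked Eif2s3y was at 4.49 and 4.45 against 4.53 and 4.66. These sex-linked transcripts thus did not set WT4 and WT5 apart from WT2 and WT3.

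The higher basement membrane and Cubn transcripts of the primitive endoderm list in KO embryos were set against adhering cells and the bioB batch. Oviduct wall or connective tissue would raise its own transcripts, but among the 7 tested members of the oviduct list, Dcn, Vim and Acta2 among them, the largest difference was 0.0761 (at most 0.45 with 2 standard errors added), against 1.25 for Col4a1 (0.77 with 2 subtracted), which argues against such cells as the cause. Col1a1 and Col3a1 were below the filter, at intensities of 23.9 and 11 in WT and 23.0 and 11.2 in KO embryos, and the labels name no sorting step. The list mean was above 0 in both bioB sets, at 0.368 in the lower of them and 0.479 in the other. Their standard errors over genes were 0.176 and 0.189. These measure the spread between genes, not between the few embryos of each set. The direction was thus the same within both sets, but this does not exclude the batch as the cause of the list's shift. An effect of the genotype is one hypothesis left, resting on 4 of 18 genes and on a list test that did not pass the main threshold.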

How the results depend on the processing

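The tests with the bioB sets, without WT4 and WT5 and with the 90th percentile or lys spike covariates were chosen only after the result was seen. The count of 85 probe sets lay between 58 and 116 under the other normalizations, filters, pseudocounts, prior, array weights, counting per gene, a difference of at least 1, the bioB block (69) and without WT4 and WT5 (73), and was 125 with the lys covariate. It was 53 with the Y-linked covariate, 130 with the 90th percentile covariate, 183 at an adjusted p of 0.1, 1 in the high-bioB and 0 in the low-bioB set alone (fewer embryos). When 1 embryo was left out it was 45 to 63, with 63 without WT3 and 61 without KO5 the nearest to 85 (fewer embryos). Apart from the small sets, the cause was not tested. In all 10 fits without 1 embryo, 32 of the 85 probe sets passed. With the embryo number as a replicate block the count was 24 and 2 lists passed. Deviations of same-numbered embryos correlated between -0.03 and 0.18 and 2 of 5 embryos matched their own number best. With so few embryos this cannot tell whether the numbers pair them. WT1, WT2, KO1 and KO2 were high-bioB arrays and WT4, WT5, KO4 and KO5 low-bioB arrays, so the numbers partly follow the technical sets. The Klf5 difference lay between -6.34 and -5.86 when 1 embryo was left out. Over the other alternatives for this probe set it ranged from -6.80 (high-bioB set alone) to -4.89 (pseudocount of 64). It was -6.79 with a pseudocount of 1 and -6.62 without WT4 and WT5. The mean of the 2 tested Klf5 probe sets differed by -2.67. The Klf5 difference passed in each of these except the low-bioB set alone (-5.05, limma adjusted p = 0.0951, range over its alternatives 3.17e-05 to 0.0951). The number of lists past camera, 0 in the main test, was 1 with the filter at the 60th percentile, 2 with the Y-linked covariate, 2 with the mean of a gene's probe sets, 2 with the bioB block, 2 in the low-bioB set, and 0 to 2 when 1 embryo was left out. It was 1 with directional fry and 7 with mixed fry. The cause was not tested. Named genes kept their side of the threshold in 2401 of their alternative fits, lost it in 158 and gained it in 19, and list calls were kept in 617 and gained in 18. Most named probe sets and all lists did not pass in the main test, so most of the kept fits passed in neither. The 158 losses fall on the named probe sets that passed in the main test. The sign of a difference changed in 24 fits of 14 named probe sets and in 70 fits of 14 lists, and 0 of these passed after the change. Signal over background limits the rest, since probe sets with a mean under 5.55 were not tested in the main comparison.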

Other observations

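The genes in the next sentences and the comparison of sex-linked transcripts were chosen only after their values were seen. Outside the rule for named genes, further transcripts fell in KO embryos past the adjusted threshold. They included Lmna, the nuclear lamina protein, from 9.32 ± 0.63 to 7.49 ± 0.45 (SD, n = 5; limma adjusted p = 0.0430), Actn1, an actin crosslinker (-1.46, adjusted p = 0.0371), and Limk2, a kinase acting on cofilin (-1.21, adjusted p = 0.0271). Emp2, an epithelial membrane protein (-1.57, adjusted p = 0.0164), Lgals4, a galectin (-1.71, adjusted p = 0.00505), and Rragd, a Rag GTPase of amino acid sensing (-1.40, adjusted p = 0.00146), fell as well. The phosphate transporter Slc20a1 (0.97, adjusted p = 0.0446), the ephrin receptor Epha4 (1.08, adjusted p = 0.0380) and the histone methyltransferase Ezh1 (0.93, adjusted p = 0.0371) rose. With the bioB block Lmna, Actn1, Slc20a1 and Ezh1 did not pass (-1.86, -1.47, 0.92 and 0.93; adjusted p = 0.0638, 0.0622, 0.0638 and 0.0638), nor did they without WT4 and WT5 (0.129, 0.115, 0.101 and 0.115). Limk2 was lost without WT4 and WT5 (0.0543), whereas Emp2, Lgals4, Rragd and Epha4 passed in both. No enrichment was tested over these genes, so no common function is claimed.

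Sex-linked transcripts set WT1 apart. Xist, the RNA of the inactive X chromosome, was at 6.73 in WT1 and between 11.17 and 13.09 in the other embryos of both genotypes. Eif2s3y, a Y-linked gene, was at 6.48 in WT1 and between 4.45 and 4.66 in the others. The sexes of the embryos are not given in the labels. Without WT1, 56 probe sets passed between the genotypes (12 higher, 44 lower in KO embryos), 45 of them among the 85.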
